A study of Mus musculus with 7 samples.

How the data were processed

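Hearts of C57BL6/J mice and of mice labelled MerTK KO, at P1 or 8 weeks of age and after myocardial infarction or a sham operation, were perfused and digested with collagenase and DNase, per the labels' protocols. Red cells were lysed, dead cells were removed by Annexin V binding, and CD45+ cells (leukocytes) were enriched and recombined with CD45- cells at 2 to 1, per the same protocols. Libraries were made with the 10x Genomics 3' chemistry, version v3 or v3.1, and sequenced on an Illumina NovaSeq. The labels do not say which library had which version, how long after surgery hearts were taken, how many hearts made a library or which part of Mertk was deleted. They do not say that the 2 WT P1 MI libraries came from separate animals either, so p-values measure the spread between these 2 samples, which may be technical. These 2 libraries were compared first: 417 of 6835 genes were at least 2-fold apart, and a chi-square of their summed counts over its degrees of freedom was 15.9. They are thus not 1 library deposited again, which does not show that they came from separate animals.

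The deposited files hold raw UMI counts per gene and barcode, not normalized, made by the authors with Cell Ranger on the mouse genome GRCm38 (mm10), per the submitters' processing notes. The series design text names Cell Ranger 4.0.0, whereas the file headers give 4.0.0 for 5 libraries and 6.1.0 for WT P1 MI replicate 2 and WT 8 week sham. The header version thus differed between the 2 WT P1 MI libraries, on which the spread of the tests rests. A filter on cells beyond the barcodes that Cell Ranger kept is not given in the sources used here. A 3' tag counts a transcript near its polyadenylation site, so counts say nothing of exons farther upstream. Gene positions were taken from GENCODE vM21 on GRCm38.

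Barcodes with at least 500 UMIs, at least 300 genes and at most 15% mitochondrial UMIs were kept. Scrublet was run per library in scanpy 1.11.5. Its automatic threshold marked only 1 cell of Mertk KO P1 MI (0.0151%) and 2 of WT 8 week MI (0.0639%), so the cells with the highest scores were removed instead, as many as 0.8% per 1000 barcodes, which took out 20, 5, 822, 1876, 78, 55 and 349 cells in the order WT P1 sham, WT P1 MI replicates 1 and 2, WT 8 week sham, WT 8 week MI, Mertk KO P1 sham and Mertk KO P1 MI. This left 36953 cells. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, chosen with library as batch key and without erythroid, mitochondrial and ribosomal genes, gave 30 principal components, a graph of 15 nearest neighbours and Leiden clusters at resolution 1 with seed 0 (leidenalg 0.10.2, scikit-learn 1.9.0). No batch integration was applied, so that values within a class were not altered. Clusters were named from marker lists fixed beforehand, by the class with the highest score of its markers. A cluster stayed unnamed where its 10 leading genes held more markers of another class, where under 3 markers were detected, or where it was shallow with no marker among its leading genes. The scoring and a rule that sets aside clusters with 5 or more markers of a second lineage as mixed were written after the data were seen.

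Raw counts were summed per library over the cells of a class, since cells are not replicates. The sums were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, TMM scaling, filterByExpr by group) in 1 fit of all 7 libraries with 6 groups and no covariate. The spread rests on the 2 WT P1 MI libraries, with 1 residual degree of freedom, and every lone library is assumed to vary like them. Only comparisons that hold WT P1 MI were tested, that is 3 contrasts and the injury by age and injury by genotype interactions, 5 per class, and adjusted p-values (Benjamini-Hochberg) are within a contrast. Genes were called at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. Errors of log2 fold changes are approximate standard errors, the absolute log2 fold change divided by the square root of the test's F statistic. Other comparisons are log2 ratios of CPM with 0.5 counts added per library, with exact intervals for counting error. Macrophages were the main class. Fibroblast, endothelial, monocyte and neutrophil classes were compared where every library held at least 30 cells. TMM scaling moved the median log2 ratio of all macrophage genes, relative to CPM, by 0.156 in WT P1 MI against sham, −0.377 in WT P1 MI against WT 8 week MI, 0.0877 in Mertk KO P1 MI against WT P1 MI, −0.137 in the age interaction and 0.0943 in the genotype interaction. In the untested comparisons it would have moved it by 0.293 (WT 8 week MI against sham), −0.240 (WT P1 sham against 8 week sham), −0.00655 (KO against WT sham) and 0.251 (KO MI against KO sham).

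Named genes follow a rule. In macrophages these are 11 genes of efferocytosis and arachidonate metabolism always named, the 8 largest and 8 smallest changes among genes with at least 50 CPM in the higher group and 30 UMIs, and up to 4 members of each list. For tested comparisons only called genes are eligible and they rank by the WT P1 MI library nearer to no change. Markers of erythroid, cardiomyocyte, neutrophil, fibroblast, endothelial, T and B cells and mitochondrial, ribosomal and sex chromosome genes are reported only as lists. Other classes have 5 at each end and 2 per list. Of these, the text gives a selection. A ratio against a group with 0 UMIs is a lower bound from 3 counts over that group. The 25 gene lists were measured over members with at least 20 UMIs, and a list's median was placed among 10000 random lists of equal size drawn from 20 bins of expression. Such a percentile compares genes within the same libraries and measures no spread between libraries or animals. Shares carry exact Clopper-Pearson intervals, and shares of cells with a UMI were computed after thinning to 1500 UMIs per cell. The groups, tests, marker and gene lists, thresholds, cell filters and the first set of alternative settings were fixed before the data were examined.

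The differential test was tested on simulated data drawn from the real macrophage means and library sizes, with 200 genes changed. For WT P1 MI against sham (10137 genes) it recovered 8.33%, 73.5%, 89.8% and 93.9% of genes changed by log2 folds of 1, 2, 3 and 4. For WT P1 MI against WT 8 week MI (10079 genes) these were 12.8%, 77.1%, 95.8% and 96.0%, and for Mertk KO P1 MI against WT P1 MI (10113 genes) 10.2%, 66.0%, 82.0% and 100.0%. False calls were 0.151%, 0.152% and 0.0403% of unchanged genes. Every simulated library was drawn with the spread of the fit, so lone libraries vary like the WT P1 MI pair by construction. The simulation therefore cannot say how many false calls the real lone libraries give. Changes of 2-fold were thus mostly missed.

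The alternative settings were stricter cell filters (1000 UMIs, 500 genes, 10% mitochondrial), no doublet removal and Scrublet's automatic threshold, Leiden resolutions 0.5 and 2, clusters built per library, macrophages merged with monocytes, DESeq2 1.42.0 with its own size factors, RLE scaling in edgeR, no filter on low counts, each WT P1 MI library left out, a pseudocount of 5, a list floor of 100 UMIs, TMM-scaled CPM, thinning to 1000 UMIs or none, and other resolutions (0.3 and 0.8) or thinning for sub-clusters. Added after the data were seen were the clusters led by macrophage markers, the WT 8 week MI library left out of the fit, called genes without those shared with fibroblasts and endothelial cells, and DESeq2 for the other classes. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9, and limma 3.58.1 within edgeR.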

Results

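Droplet single-cell RNA sequencing was applied to hearts of mice that had undergone myocardial infarction (MI) or a sham operation, at an age labelled P1 (the neonatal period, when the mouse heart can still regenerate) or 8 weeks. The 7 libraries fell into 6 groups. WT P1 MI had 2 libraries, and WT P1 sham, WT 8 week sham, WT 8 week MI, Mertk KO P1 sham and Mertk KO P1 MI had 1 each. WT animals were C57BL6/J, a common inbred laboratory strain. The other animals were labelled MerTK KO. Mertk is a receptor tyrosine kinase with which macrophages bind and engulf apoptotic cells, a process called efferocytosis. The series addresses efferocytosis at an early age, the metabolism of arachidonic acid in macrophages and regeneration of the heart. Arachidonic acid is the membrane fatty acid from which prostaglandins, thromboxane and leukotrienes are made.

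The deposited counts held 44318 barcodes and 367475379 UMIs (unique molecular identifiers, 1 per captured transcript) over 32285 genes. Total UMIs per library were 21019995 in WT P1 sham, 13318734 and 130847843 in WT P1 MI replicates 1 and 2, 114677538 in WT 8 week sham, 7707724 in WT 8 week MI, 29769711 in Mertk KO P1 sham and 50133834 in Mertk KO P1 MI. In the same order, the cells kept after filtering numbered 1570, 768, 9313, 13436, 3052, 2556 and 6258. Their median UMIs per cell were 9177, 11372, 8476, 3625, 2136, 8414 and 4636. Values for all 7 libraries are listed in this order throughout. Intervals are exact 95% intervals and cover counting error only.

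Clusters were named by markers fixed beforehand and are called X-like. Macrophage-like cells numbered 240, 83, 623, 151, 1707, 136 and 182, and different clusters held most of them in different libraries. Cluster 17, led by Mrc1, Cbr2, Fcrls, Folr2 and Hpgds, genes of tissue macrophages, held 54.2% of the class in WT P1 sham, 55.4% and 62.8% in WT P1 MI, 39.1% in WT 8 week sham, 69.8% in Mertk KO P1 sham and 35.7% in Mertk KO P1 MI. Cluster 6, led by Ms4a7, Ccl8, Gpnmb, Mmp12 and Spp1, held 91.7% of the class in WT 8 week MI. The cycling cluster 33 held 48.4% of it in Mertk KO P1 MI, and the cycling cluster 37 held 27.8% in WT 8 week sham. The shallow cluster 32 held 34.2% of it in WT P1 sham and 36.1% and 15.4% in WT P1 MI, and cluster 33 held 18.9% of it in WT P1 MI replicate 2. The term clusters led by macrophage markers refers to clusters 6 and 17 alone, a restriction chosen after the data were seen, with 131, 46, 408, 80, 1578, 100 and 71 cells. Median UMIs per macrophage-like cell were 9998, 10734, 10010, 10058, 2201, 9556 and 9494, with WT 8 week MI by far the shallowest.

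Mertk (ENSMUSG00000014361; GRCm38 chromosome 2, 128698956 to 128802894, plus strand) was measured in every library. In macrophage-like cells it reached 47.4 CPM (summed UMIs scaled to a common library total; interval 39.3 to 56.8) in WT P1 sham, 37.2 (26.0 to 51.5) and 22.1 (18.9 to 25.7) in the WT P1 MI libraries, 38.9 (31.0 to 48.3) in WT 8 week sham, 30.8 (25.8 to 36.6) in WT 8 week MI, 37.5 (28.3 to 48.7) in Mertk KO P1 sham and 13.8 (9.22 to 19.8) in Mertk KO P1 MI. These rest on 119, 36, 166, 82, 130, 56 and 29 UMIs. Tyro3, a receptor of the same family, had at most 1 UMI in any library. Mertk transcripts were thus counted in both knockout libraries. In neutrophil-like cells they were higher there, at 15.8 and 23.0 CPM (42 and 228 UMIs) in the sham and MI libraries, against 0 UMIs in 4 of the WT libraries and 1.39 CPM (5 UMIs) in WT P1 MI replicate 2. Of these 4, WT 8 week sham held 831 neutrophil-like cells. WT P1 sham, WT P1 MI replicate 1 and WT 8 week MI held only 44, 17 and 5, so 0 UMIs show little there. The counts are 3' tags and the labels do not say which part of the gene was deleted, so this level checks neither the genotype labels nor the loss of the protein.

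The libraries also differed in the sex of their animals. Over all cells, Xist, which is transcribed from the inactive X chromosome of females, was at 340.7, 935, 418, 0.0361, 0, 763.5 and 46.5 CPM, and the Y-linked gene Ddx3y at 83.3, 16.5, 15.05, 69.1, 65.7, 0 and 50.85 CPM. Xist was thus higher in Mertk KO P1 sham than in WT P1 sham and lower in Mertk KO P1 MI than in WT P1 MI, and the 8 week libraries held almost none. Ddx3y was lower in both WT P1 MI libraries than in WT P1 sham. It was called lower there in macrophage-like (−1.61 ± 0.38), endothelial-like (−2.85 ± 0.36) and monocyte-like cells (−2.93 ± 0.54). Sex was therefore not separated from injury at P1 in either genotype, from genotype, from age after MI or between the sham libraries, or from either interaction. Neither was the Cell Ranger version given in the headers separated from MI at 8 weeks, from age between the WT sham libraries or from the age interaction.

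Among named immune cells, macrophage-like cells made up 27.6% (24.6 to 30.7) of the WT P1 sham library, 29.96% (24.6 to 35.7) and 28.4% (26.5 to 30.3) of the WT P1 MI libraries, 1.86% (1.57 to 2.17) of WT 8 week sham, 87.9% (86.4 to 89.3) of WT 8 week MI, 9.40% (7.94 to 11.0) of Mertk KO P1 sham and 3.53% (3.05 to 4.07) of Mertk KO P1 MI. Neutrophil-like cells made up 5.06% (3.70 to 6.73), 6.14% (3.62 to 9.65), 28.4% (26.5 to 30.3), 10.2% (9.56 to 10.9), 0.258% (0.0837 to 0.600), 37.8% (35.3 to 40.4) and 56.4% (55.0 to 57.7). Monocyte-like cells made up 5.98%, 11.6%, 24.9%, 5.75%, 0.824%, 25.0% and 33.5%. B cell-like cells made up 32.9%, 19.9%, 6.66%, 40.0%, 4.74%, 8.02% and 1.15%, and T cell-like cells 19.9%, 22.0%, 4.47%, 20.9%, 1.70%, 11.1% and 2.87%. The 2 WT P1 MI libraries lay apart by more than counting error in neutrophil-like cells (mean 17.3% ± 15.7, SD, n = 2), monocyte-like cells (18.2% ± 9.46), B cell-like cells (13.3% ± 9.34) and T cell-like cells (13.2% ± 12.4), but not in macrophage-like cells (29.2% ± 1.11). No difference in shares between groups was therefore tested. Over 7 settings of cell filters, doublet removal and clustering, macrophage-like shares ran from 24.5% to 30.5%, 21.4% to 36.5%, 24.7% to 38.2%, 1.42% to 8.63%, 30.9% to 93.4%, 8.30% to 20.5% and 2.03% to 23.7%, and monocyte-like shares from 5.85% to 6.74%, 8.24% to 13.3%, 7.68% to 32.4%, 5.75% to 7.13%, 0.376% to 16.9%, 10.04% to 25.2% and 12.97% to 34.5%. In WT 8 week MI the B cell-like share ran from 1.38% to 14.2% and the T cell-like share from 0.439% to 6.30%, and in Mertk KO P1 MI they ran from 1.13% to 1.60% and from 2.83% to 4.08%. With clusters built per library the macrophage-like share was 30.9% in WT 8 week MI and 17.0% in Mertk KO P1 MI.

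CD45+ cells were enriched and mixed with CD45- cells at 2 to 1, hearts were perfused, red cells were lysed and apoptotic cells were removed, so shares describe the cells loaded and not the tissue. Median UMIs of neutrophil-like cells ran from 646 in WT 8 week MI to 4848 in WT P1 MI replicate 2, close to the minimum of 500 in the former. Clusters left without a name held 10.8%, 17.2%, 18.0%, 8.46%, 28.6%, 12.1% and 3.48% of all cells, and clusters with markers of more than 1 lineage, a rule set after the data were seen, held 2.93%, 2.21%, 5.99%, 2.08%, 0.262%, 1.60% and 1.84%. Cluster 14, led by Alox15 and Prg4, held 853 cells of WT 8 week sham, and cluster 15, led by Chil3 and Arg1, held 832 of WT 8 week MI. Both were of macrophage or monocyte type and stayed unnamed. Macrophage-like, monocyte-like and such unnamed mononuclear clusters together held 18.8%, 16.8%, 12.9%, 11.1%, 84.3%, 20.7% and 30.5% of all cells.

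**Figure D1:**
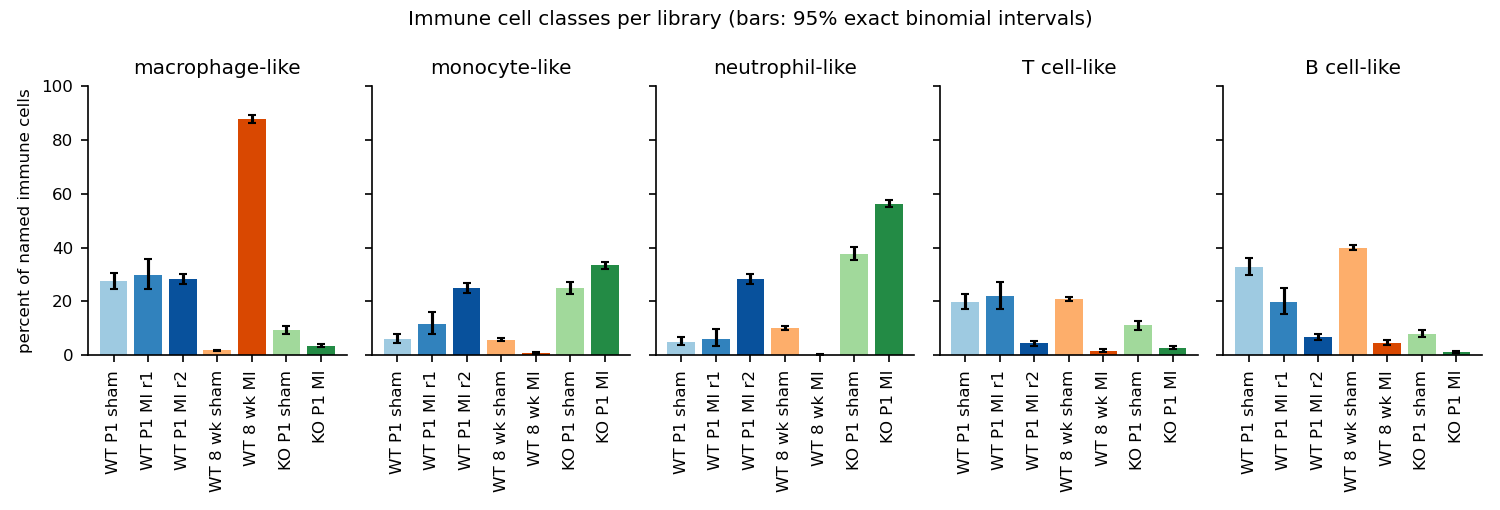
Percent of named immune cells (vertical axis, 0 to 100%) in 5 classes for each of the 7 libraries (horizontal axis; r1 and r2 are replicates); bars are the measured share and whiskers exact 95% binomial intervals, which cover counting error only. Macrophage-like cells are 87.9% of WT 8 week MI (30.9% to 93.4% over 7 settings) and 3.53% of Mertk KO P1 MI (2.03% to 23.7%), and the 2 WT P1 MI libraries differ in neutrophil-like cells (6.14% and 28.4%).

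The genes of arachidonate metabolism were first read in each library. Ptgs1 (ENSMUSG00000047250), the constitutive cyclooxygenase that makes prostaglandin H2, was at 102, 99.1, 72.2, 161, 21.1, 81.0 and 37.0 CPM in macrophage-like cells. Tbxas1 (ENSMUSG00000029925), which turns prostaglandin H2 into thromboxane A2, was at 97.3, 99.1, 63.4, 92.6, 85.1, 99.1 and 38.0 CPM. Ptgs2 (ENSMUSG00000032487), the inducible cyclooxygenase, was at 11.6, 9.30, 69.8, 125, 48.1, 54.9 and 64.6 CPM. Hpgds, the haematopoietic prostaglandin D synthase, was at 244, 144, 130.2, 35.6, 134, 151 and 53.7 CPM. Gas6 (ENSMUSG00000031451), which bridges phosphatidylserine on dying cells to Mertk and Axl, was at 273, 205.5, 100.4, 43.7, 60.9, 152 and 29.9 CPM, and its receptor Axl (ENSMUSG00000002602) at 61.0, 70.2, 45.1, 48.4, 39.6, 82.3 and 15.2 CPM.

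Shares of macrophage-like cells with a UMI were compared after thinning each cell to 1500 UMIs, which left out 50, 16, 76, 13, 391, 15 and 12 shallower cells. Ptgs1 was then seen in 13.2%, 16.4%, 11.0%, 18.8%, 3.80%, 13.2% and 5.29% of cells, and without thinning in 45.4%, 48.2%, 46.1%, 50.3%, 4.98%, 39.7% and 28.0%. T cell-like cells, which should lack Ptgs1, showed it in 0 of 171, 0 of 61 and 0 of 97 cells of the first 3 libraries at median depths of 7434, 6781 and 4747 UMIs, against 12460, 12651 and 10825 in the macrophage-like cells. In WT 8 week MI, fibroblast-like cells showed it in 7 of 137 cells (5.11%, median depth 3550), so the 3.80% of macrophage-like cells (median depth 2558) was not above that of another class there. This does not measure background, since fibroblast-like cells were not shown to lack Ptgs1. Tbxas1 was seen in 14.7%, 14.9%, 11.7%, 12.3%, 10.9%, 14.9% and 8.24% after thinning and in 49.2%, 45.8%, 46.4%, 54.3%, 17.3%, 52.2% and 28.6% before. Timd4, an engulfment receptor of resident macrophages, was seen after thinning in 3.62% of WT 8 week sham cells and in 0 of 1316 WT 8 week MI cells, at median depths before thinning of 10460 and 2558 UMIs. The latter allows up to 0.228% of cells with a UMI and does not limit the cells that express the gene. As background, 0 of 1506 fibroblast-like cells (8837 UMIs) showed it in WT 8 week sham and 1 of 137 (0.73%, 3550 UMIs) in WT 8 week MI.

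**Figure D2:**
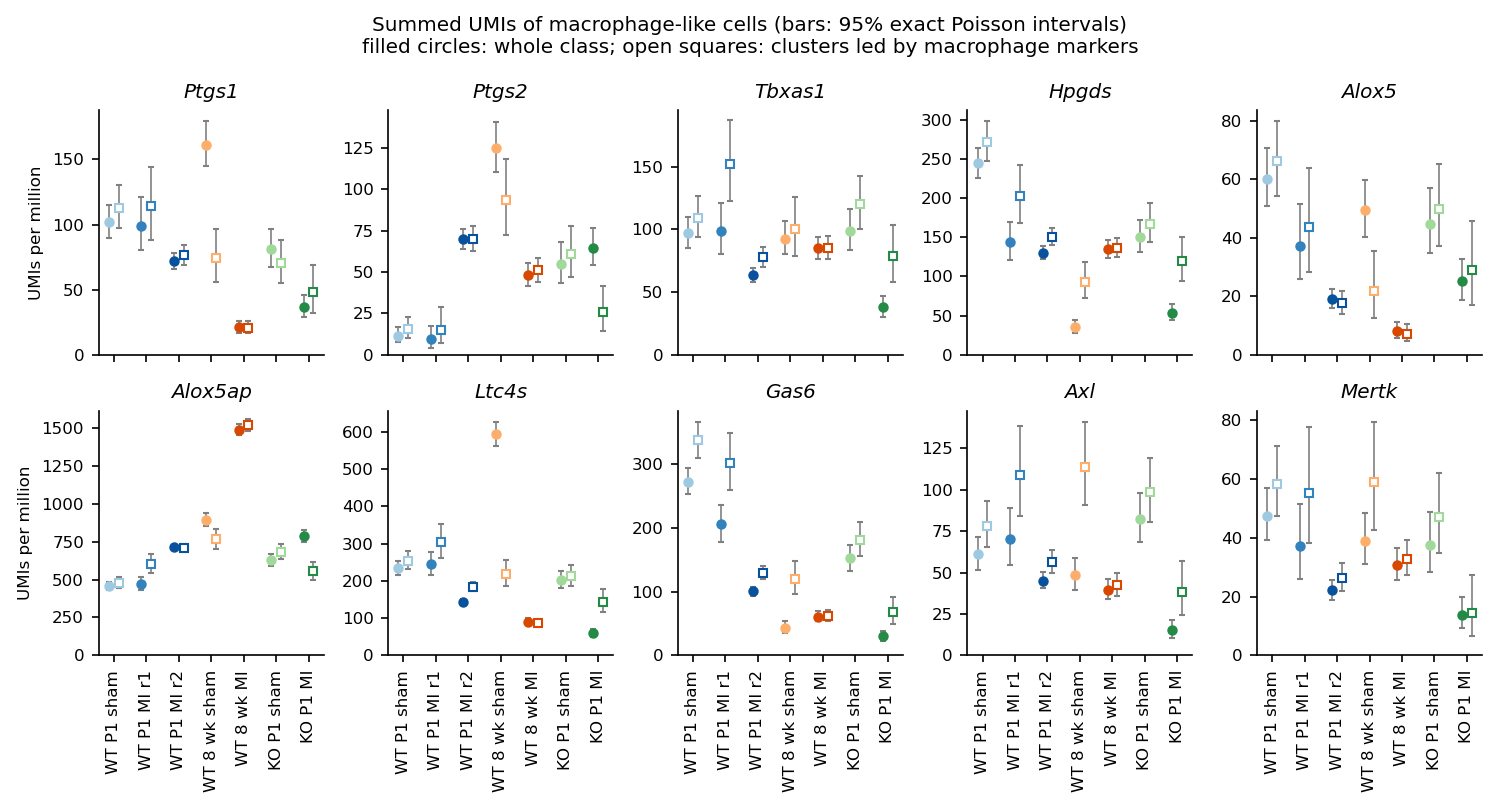
Expression in CPM (vertical axis, linear, from 0) of 10 genes in each of the 7 libraries (horizontal axis); filled circles are all macrophage-like cells, open squares the clusters led by macrophage markers, and bars exact 95% Poisson intervals (counting error only). Ptgs1 is lowest in WT 8 week MI (21.1 CPM), and Gas6 and Axl are lowest in Mertk KO P1 MI (29.9 and 15.2 CPM).

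The injury response of the neonate was read from WT P1 MI against WT P1 sham. Genes of monocytes and newly recruited macrophages were higher after MI: Ly6c2, a surface protein of inflammatory monocytes, rose by a log2 fold change of 6.49 ± 0.64 (SE), and Fn1, fibronectin, rose by 5.30 ± 0.71, from 8.37 CPM in the sham library to 399 and 209.6 CPM. Of the 12 tested genes of the MHC class II complex, which presents antigen to helper T cells, H2-Eb1 (2.93 ± 0.56), H2-Aa (2.82 ± 0.58) and H2-Ab1 (2.69 ± 0.57) rose, but the list's median log2 ratio was 0.145 and these 3 were at −0.64, −0.86 and −1.09 with clusters built per library. Other genes that rose were Gpnmb, a glycoprotein of lysosomes (4.23 ± 0.69), Fabp5, a fatty acid binding protein (1.82 ± 0.49), the scavenger receptor Marco (3.60 ± 0.62) and Areg, the growth factor amphiregulin (3.42 ± 0.48). Saa3, an acute-phase protein, and Arg1, arginase, had 0 UMIs in the sham library and were at least 182-fold and at least 68.7-fold higher, with Saa3 at 124 and 311 CPM and Arg1 at 142.5 and 21.8 CPM in the 2 MI libraries. Several of these were smaller without replicate 2, when the log2 ratio was 1.17 for Gpnmb, 1.37 for Marco and 2.27 for Areg. Cd209f, a lectin of resident macrophages, fell (−2.33 ± 0.58, from 31.5 CPM to 0 and 7.32 CPM).

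In the thromboxane and prostanoid synthesis list, 1 of 12 tested members rose, and 1 did when adjusted over the list alone. It was Ptgs2 (2.16 ± 0.49, adjusted p 0.00166 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), which rested on replicate 2 and was −0.26 without it. No call was made for Ptgs1 (−0.12 ± 0.37) or Tbxas1 (−0.14 ± 0.38). Of the eicosanoid receptors, 2 of 7 rose (2 adjusted over the list alone), the leukotriene B4 receptor Ltb4r1 (4.40 ± 0.55) and the formyl peptide and lipoxin receptor Fpr2 (3.06 ± 0.62, and 1.37 without replicate 2). Of 29 efferocytosis genes, 4 rose (4 adjusted over the list alone), Marco, Olr1, Cd300lf and Thbs1, the last of which was −0.064 without replicate 2. Mertk (−0.61 ± 0.36), Axl (0.03 ± 0.37) and Gas6 (−0.73 ± 0.38) were not called. Of 20 monocyte-derived macrophage genes 16 rose (18 adjusted over the list alone), of 12 MHC class II genes 3 (5), of 19 interferon response genes 2 (7), of 22 growth factors 2 (3), Areg and Nrg1, and of 31 efferosome and lysosome genes 4 (5), while 1 of 21 resident macrophage genes fell. Neutrophil markers moved with these groups, since 13 of 14 rose (14 adjusted over the list alone) with a median log2 fold of 4.69, or 3.79 with genes absent from the sham library at their bound. Their UMIs lay mainly in the cycling cluster 33, which held 6 of the 83 macrophage-like cells of replicate 1 and 118 of the 623 of replicate 2. From the sham library to replicates 1 and 2, the markers summed to 79.7, 17963 and 18587 CPM in the class and to 72.9, 107 and 2510 CPM in the clusters led by macrophage markers.

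Of 10655 genes tested in macrophage-like cells, 219 were called (204 higher, 15 lower), at an adjusted p under 0.05 and a log2 fold of at least 1, with the lone sham library assumed to vary like the 2 WT P1 MI libraries. DESeq2 called 52, 50 of them shared, and edgeR called 42 without doublet removal. The clusters led by macrophage markers gave 117, of which 99 were shared, and clusters built per library gave 0 by edgeR, where 368 genes had an unadjusted p under 0.05.

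The same infarct libraries were set against WT 8 week MI to compare ages after injury. Ptgs1 was higher in the neonate by 1.62 ± 0.41 (adjusted p 0.00156 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), as were Hpgd, which degrades prostaglandins (3.05 ± 0.47), and Alox5, the 5-lipoxygenase that starts leukotriene synthesis (1.30 ± 0.42), while its activating protein Alox5ap was lower (−1.68 ± 0.48). The resident macrophage genes Timd4 (4.60 ± 0.68), Lyve1, the hyaluronan receptor (3.09 ± 0.49), and Cd163, the haemoglobin scavenger receptor (1.89 ± 0.46), were higher at P1. Without replicate 1 Lyve1 was at 2.00, Cd163 at 1.14 and Alox5ap at −1.07, and without replicate 2 Cd163 was at 3.16 and Alox5 at 2.20. Spp1, the secreted matrix protein osteopontin, was at 294 and 411 CPM in the neonatal libraries and 13752 CPM in the adult (−5.64 ± 0.62), and Ccl8, Gpnmb and the cathepsin Ctsb were lower at P1 too (−5.59 ± 0.43, −4.13 ± 0.45 and −2.91 ± 0.59, with Gpnmb at −6.59 without replicate 2). The interferon-induced genes Ifit1 (−4.04 ± 0.40) and Oas1a (−3.70 ± 0.36) and the glycolytic enzyme Eno1 (−2.22 ± 0.45, and −1.38 without replicate 2) were also lower at P1, and the proliferation marker Mki67 was higher (3.36 ± 0.52).

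By list, thromboxane and prostanoid genes had 4 of 12 higher and 0 lower, also adjusted over the list alone, namely Ptgs1, Hpgd, Ptges2 and Ptges3. Tbxas1 (−0.48 ± 0.37) and Ptgs2 (−0.42 ± 0.40) were not called. Lipoxygenase and leukotriene genes went both ways, with 3 of 11 higher and 3 lower (3 and 4 adjusted over the list alone). Efferocytosis genes had 4 of 29 higher and 10 lower (5 and 11), among the latter Mfge8, a bridging molecule (−2.16 ± 0.37, and −1.42 without replicate 1). Mertk, Axl and Gas6 were not called (−0.52 ± 0.36, 0.12 ± 0.37 and 0.90 ± 0.41). Resident macrophage genes had 6 of 21 higher and 2 lower (8 and 2), efferosome and lysosome genes 0 of 31 higher and 16 lower (16), MHC class II genes 7 of 12 lower (8), interferon genes 15 of 19 lower (15), glycolysis genes 6 of 16 lower (6) and cell cycle genes 12 of 24 higher (12), each figure in brackets adjusted over the list alone. Cardiomyocyte transcripts moved with age, with 11 of 11 higher at P1 and a median of 4.66, or 4.52 at the bound. The mitochondrially encoded list (median log2 ratio 1.30) and the dissociation and immediate early list (1.07) were higher at P1 too, with no change of sign under 8 alternative settings.

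In all, 2555 genes were called (1353 higher at P1, 1202 lower), against 467 by DESeq2, 456 of them shared, 1118 by edgeR without doublet removal and 1530 in the clusters led by macrophage markers, 1467 shared. The WT 8 week MI library is the shallowest, stood apart in the same direction in several cell classes, and 800 of the called genes were at least 2-fold apart on the same side in fibroblast-like and endothelial-like cells too, so the effect of age was not separated from that of the library. Nor was it separated from the mix of clusters. Cluster 17 held 46 and 391 cells of the WT P1 MI libraries and 13 of WT 8 week MI. Cluster 6 held 17 of replicate 2 and 1565 of WT 8 week MI. The clusters led by macrophage markers thus also compare mainly cluster 17 with cluster 6, and the calls shared with them do not remove this difference.

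Mertk KO P1 MI, 1 library, was set against WT P1 MI. The cycling cluster 33 gave 1357974 of the 2105763 macrophage-like UMIs of the knockout, against 225988 of 968288 and 2426260 of 7509384 in WT P1 MI. In the knockout, neutrophil markers were at 28724 CPM in that cluster. Axl was at 5.89 and Gas6 at 14.0 CPM in it, against 35.2 and 77.7 CPM in cluster 17. The receptor's loss was thus not separated from the mix of clusters, nor from sex. Axl, the related engulfment receptor, was lower in the knockout by −1.79 ± 0.43 (adjusted p 0.00547, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and Gas6 by −2.22 ± 0.46 (0.0005), with 205.5 and 100.4 CPM in WT and 29.9 CPM in the knockout. Ltc4s, leukotriene C4 synthase, and Lta4h, leukotriene A4 hydrolase, were lower (−1.56 ± 0.46 and −1.44 ± 0.41, the latter −0.76 without replicate 1), and so was Hpgd (−1.67 ± 0.43), while the inducible prostaglandin E synthase Ptges was higher (5.11 ± 0.71, from 1.03 and 0.932 to 33.7 CPM). Marco (4.19 ± 0.43), Saa3 (4.42 ± 0.52), Acod1, which makes the metabolite itaconate (3.05 ± 0.38, and 6.14 without replicate 2), and the interferon-induced genes Cxcl9 (0 and 0.266 CPM in WT, 34.7 CPM in the knockout), Rsad2 (2.70 ± 0.41) and Ifit3 (2.35 ± 0.42, but −0.88 with clusters built per library) were higher in the knockout. The resident macrophage genes Fcna, a ficolin (−2.96 ± 0.50), and Timd4 (−2.71 ± 0.59) were lower, as were the growth factors Igf1 (−2.09 ± 0.48) and Bmp2 (−2.11 ± 0.44).

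Ptgs1 (−1.10 ± 0.41, adjusted p 0.151), Tbxas1 (−0.97 ± 0.41, 0.242), Hpgds (−1.26 ± 0.42, 0.0935) and Mertk itself (−0.93 ± 0.42, 0.308) were not called by edgeR's quasi-likelihood test. Of 12 thromboxane and prostanoid genes, 1 was higher and 1 lower (1 and 3 adjusted over the list alone), of 11 lipoxygenase genes 0 and 2 (1 and 4), of 29 efferocytosis genes 2 and 6 (3 and 7), with Mfge8 (2.00 ± 0.37, and 3.10 without replicate 2) and Marco higher, and of 7 eicosanoid receptors 2 and 0 (2 and 0), Fpr2 and Ltb4r1, the latter of which turned to −0.33 with strict cell filters and −1.24 in the clusters led by macrophage markers. Of 21 resident macrophage genes 9 were lower (13), of 20 monocyte-derived genes 6 were higher and 1 lower (8 and 1), of 19 interferon genes 3 were higher (6), of 16 glycolysis genes 4 higher (9), of 24 cell cycle genes 3 higher (3; Tpx2, Ccnb1 and Cenpf turned to −0.51, −0.30 and −0.61 with monocytes merged and to −0.50, −0.0098 and −0.55 with clusters built per library), and of 24 cytokines 2 were higher and 4 lower (5 and 7). Neutrophil markers were higher for 5 of 14 and lower for 1 (7 and 2), and B cell markers lower for 8 of 11 (11). Cardiomyocyte markers had a median of −2.27, or −2.19 at the bound, mitochondrially encoded genes of −0.734 and dissociation and immediate early genes of −0.528. T cell markers had one of 1.78, which turned to −1.11 under 1 of 8 alternative settings.

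The test called 279 genes (121 higher in the knockout, 158 lower), DESeq2 20 (2 higher, 18 lower; 19 shared), and edgeR 3 without doublet removal. In the clusters led by macrophage markers 47 were called, 36 of them shared. There Cxcl9, Rsad2, Ifit3, Mfge8, Marco, Gpnmb (−0.21 with monocytes merged) and Fcna stayed past the test, and Axl (−1.01 ± 0.54, adjusted p 0.815), Gas6 (−1.60 ± 0.56, 0.288), Ltc4s and Timd4 did not, by edgeR's quasi-likelihood test.

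Whether the injury effect differs with age was tested as an interaction, (WT P1 MI minus sham) minus (WT 8 week MI minus sham). Ptgs2 (3.24 ± 0.67, adjusted p 0.000219 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and Ptgs1 (2.52 ± 0.59, 0.00136) were more positive in the neonate, with Hpgd (2.34 ± 0.63) and Ltc4s (2.26 ± 0.66, but −1.36 without doublet removal), and Hpgds was more negative (−2.89 ± 0.61, 0.000284). The thromboxane and prostanoid list had 4 of 12 higher and 1 lower, also adjusted over the list alone, and a median of 1.14, at percentile 99.5 of random lists of equal size and expression. It ran from 0.228 (without doublet removal) to 1.32 over 8 alternative settings. Ptgs2 was at 1.11 without replicate 2. In WT 8 week sham the cycling cluster 37 gave 950556 of the 2106380 macrophage-like UMIs. It had Ptgs1 at 290 and Hpgds at 4.21 CPM there, against 97.4 and 111 CPM in cluster 17. Cluster 37 held 1 cell in each WT P1 library, so for Ptgs1 and Hpgds the age interaction was not separated from the mix of clusters. Monocyte-derived genes had 15 of 20 higher (16 adjusted over the list alone), among them Fn1 (8.44 ± 0.94) and Ly6c2 (7.90 ± 0.79). Resident macrophage genes went 5 higher and 5 lower of 21 (5 and 6), and neutrophil markers 7 of 14 higher. Cardiomyocyte markers had a median of 1.92, B cell markers of 1.34, erythroid markers of −2.63 and dissociation and immediate early genes of 0.963. T cell markers were at −0.679, with the opposite sign in 4 of 8 alternative settings.

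In all, 979 genes were called (704 higher, 275 lower), against 167 by DESeq2, 150 of them shared, and 252 in the clusters led by macrophage markers, 224 shared. Without doublet removal edgeR called 0, with 1285 genes at an unadjusted p under 0.05. Of the genes above, Ptgs2 stayed past the test in those clusters (2.39, adjusted p 0.034 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and Ptgs1 (1.43, 0.401), Hpgds (−1.32, 0.486) and Ltc4s did not. In the whole class DESeq2's adjusted p was 1 for Ptgs2, 0.165 for Ptgs1 and 0.0187 for Hpgds.

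Whether the injury effect differs with genotype was tested in the same way, (Mertk KO P1 MI minus sham) minus (WT P1 MI minus sham). Axl was the only one of the 11 always named genes past the test (−2.21 ± 0.60, adjusted p 0.0374 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), with log2 effects of −2.42 in the knockout and −0.11 in WT. Monocyte-derived genes had 7 of 20 lower (9 adjusted over the list alone), resident macrophage genes 3 of 21 (9), MHC class II genes 3 of 12 (4) and efferocytosis genes 3 of 29 (4), namely Cd163 (−3.80 ± 0.67), Timd4 (−3.24 ± 0.79) and Axl. The thromboxane and prostanoid list had a median of −0.82, at percentile 0.1 of random lists of equal size and expression, but none of its 12 members passed the test. That percentile ranks genes and measures no spread between libraries. The median was −0.41 with strict cell filters and −0.26 in the clusters led by macrophage markers. By edgeR Ptgs2 was at −1.68 ± 0.68 (unadjusted p 0.0151), Tbxas1 at −0.99 ± 0.59 (0.0972) and Ptgs1 at −0.76 ± 0.59 (0.201), and DESeq2 gave each an adjusted p of 1. Neutrophil markers were lower for 7 of 14 (9 adjusted over the list alone), erythroid, B cell and cardiomyocyte markers had medians of −4.69, −3.53 and −1.98, and mitochondrially encoded genes one of −0.632. T cell markers went the other way, with a median of 1.85 that turned to −0.768 under 1 of 8 alternative settings. The count was 113 (11 higher, 102 lower), 29 by DESeq2, all of them shared, 9 by edgeR without doublet removal and 76 in the clusters led by macrophage markers, 53 shared. In those clusters Axl was at −1.31 with an adjusted p of 1 by edgeR's quasi-likelihood test, DESeq2 gave it 1 in the whole class, and many of the lower genes had 0 UMIs in WT P1 sham.

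The remaining comparisons had 1 library on each side. They have no replicate check and no test, and genes are named by a fixed rule of size. In WT 8 week MI against WT 8 week sham, Spp1 was higher by a log2 ratio of 4.36 (4.28 to 4.43), from 671 to 13752 CPM, with the chemokine Ccl7 (3.75, 3.56 to 3.97), Ctsb (2.97, 2.92 to 3.03) and Ifit1 (4.69, 3.59 to 6.46). Ptgs1 was lower at −2.93 (−3.29 to −2.60), from 161 to 21.1 CPM, as were Ptgs2 (−1.38, −1.65 to −1.11), Alox5 (−2.60, −3.22 to −2.04), Ltc4s (−2.71, −2.88 to −2.54), Hpgd (−3.22, −3.66 to −2.82), Fn1 (−3.43, −3.51 to −3.36) and Timd4 (−4.99, −7.52 to −3.58). Hpgds was higher (1.91, 1.57 to 2.28), and Tbxas1 was at −0.12 (−0.38 to 0.14). Alox15, the 12/15-lipoxygenase of peritoneal-type macrophages, and Prg4, lubricin, were far lower, at −8.32 (−11.69 to −6.78) and −9.48 (−11.24 to −8.39). The thromboxane and prostanoid list had a median of −1.37, at percentile 0.155 of random lists, which turned to 0.127 without doublet removal and was −0.24 in the clusters led by macrophage markers, where Ptgs1 was at −1.84 and Hpgds at 0.54. The interferon list had a median of 1.33 (0.38 in those clusters), and the cell cycle list one of −1.65, which turned to 0.75. B cell markers had a median of −1.44, neutrophil markers of 1.05, dissociation and immediate early genes of −0.999 and mitochondrially encoded genes of −0.463. The sham cells lay mainly in clusters 17 and 37 and the infarct cells in cluster 6, at 10058 and 2201 median UMIs per cell.

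Between the sham libraries, WT P1 exceeded WT 8 week in Gas6 by a log2 ratio of 2.63 (2.33 to 2.97; 273 and 43.7 CPM), Hpgds by 2.77 (2.43 to 3.14) and the mannose receptor Mrc1 by 2.86 (2.70 to 3.02). It was lower in Ptgs2 (−3.41, −4.04 to −2.88), Fn1 (−8.91, −9.63 to −8.33) and H2-Aa (−5.01, −5.25 to −4.78). Ptgs1 was at −0.66 (−0.90 to −0.42) and Tbxas1 at 0.07 (−0.21 to 0.35). In cluster 17 alone the gaps were smaller, with Gas6 at 337 CPM in WT P1 sham and 155 CPM in WT 8 week sham. In the same order Hpgds was there at 272 and 111 CPM, Mrc1 at 1422 and 543 CPM and Ptgs1, now on the other side, at 113 and 97.4 CPM. The cycling cluster 37 held 42 cells of WT 8 week sham, with Gas6 at 3.16, Hpgds at 4.21 and Ptgs1 at 290 CPM, and 1 cell of WT P1 sham. Igf2bp3, a fetal RNA-binding protein, was higher at 5.56 (4.21 to 8.07). Saa3, Prg4, Arg1 and Alox15 had 0 UMIs in WT P1 sham and were at least 1188-fold, 779.8-fold, 536.0-fold and 158.4-fold lower there. Resident macrophage genes had a median of 1.30 and monocyte-derived genes one of −3.52. Neutrophil markers were at −3.84, cardiomyocyte markers at 2.64, B cell markers at −1.22 and mitochondrially encoded genes at 1.08, and the cell cycle median of −0.38 became 1.61 in the clusters led by macrophage markers.

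The sham libraries of the 2 genotypes differed without infarction. Sex differed between them too, and the time after the sham operation is not given. Mertk KO P1 sham exceeded WT P1 sham in Ptgs2 by 2.23 (1.62 to 2.91; 54.9 and 11.6 CPM), in Fn1 by 6.02 (5.43 to 6.75), in Marco by 5.38 (4.51 to 6.60), in the osteoclast phosphatase Acp5 by 5.51 (5.13 to 5.93) and in H2-Ab1 by 2.46 (2.19 to 2.74). Saa3, Arg1, Ccl8 and Acod1 had 0 UMIs in WT P1 sham and were at least 185.8-fold, 133.2-fold, 57.7-fold and 42.5-fold higher. Gas6 was lower (−0.84, −1.07 to −0.62), Axl was at 0.43 (0.08 to 0.78), Ptgs1 at −0.33 (−0.66 to −0.02) and Tbxas1 at 0.03 (−0.28 to 0.33). Eif3j1, a translation initiation factor subunit, was lower (−3.11, −3.77 to −2.56). Monocyte-derived genes had a median of 2.26, interferon genes of 1.18, neutrophil markers of 7.29, or 5.69 at the bound, and erythroid markers of 5.42.

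Within the knockout, where sex also differed between the 2 libraries, MI against sham gave lower Axl (−2.42, −3.05 to −1.87; 82.3 to 15.2 CPM), Gas6 (−2.34, −2.77 to −1.94), Mertk (−1.43, −2.14 to −0.77), Tbxas1 (−1.38, −1.79 to −0.98), Ptgs1 (−1.12, −1.56 to −0.71), Ltc4s (−1.74, −2.06 to −1.44), Cd163 (−3.97, −4.85 to −3.27) and Ctsk, cathepsin K (−4.59, −5.06 to −4.18). It gave higher Ptges (2.96, 1.88 to 4.56), Ccl5 (4.50, 3.53 to 5.92) and Saa3 (4.36, 4.20 to 4.52). Resident macrophage genes had a median of −2.04, with 18 of 20 at least 2-fold lower, and efferocytosis genes of −0.95. Markers of other cell types moved as well, with medians of −6.06 for erythroid, −4.19 (−3.97 at the bound) for B cell, −1.29 for cardiomyocyte, 1.56 for T cell and 1.09 for neutrophil markers, the last of which turned to −0.282 under 1 of 6 alternatives, and of −0.82 for mitochondrially encoded genes. Cluster 17 held most of the sham cells and the cycling cluster 33 the largest part of the infarct cells; in the clusters led by macrophage markers Axl was at −1.33, Gas6 at −1.41, Tbxas1 at −0.60 and the resident median at −1.14, while the monocyte-derived median of 0.94 turned to −0.40.

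**Figure D3:**
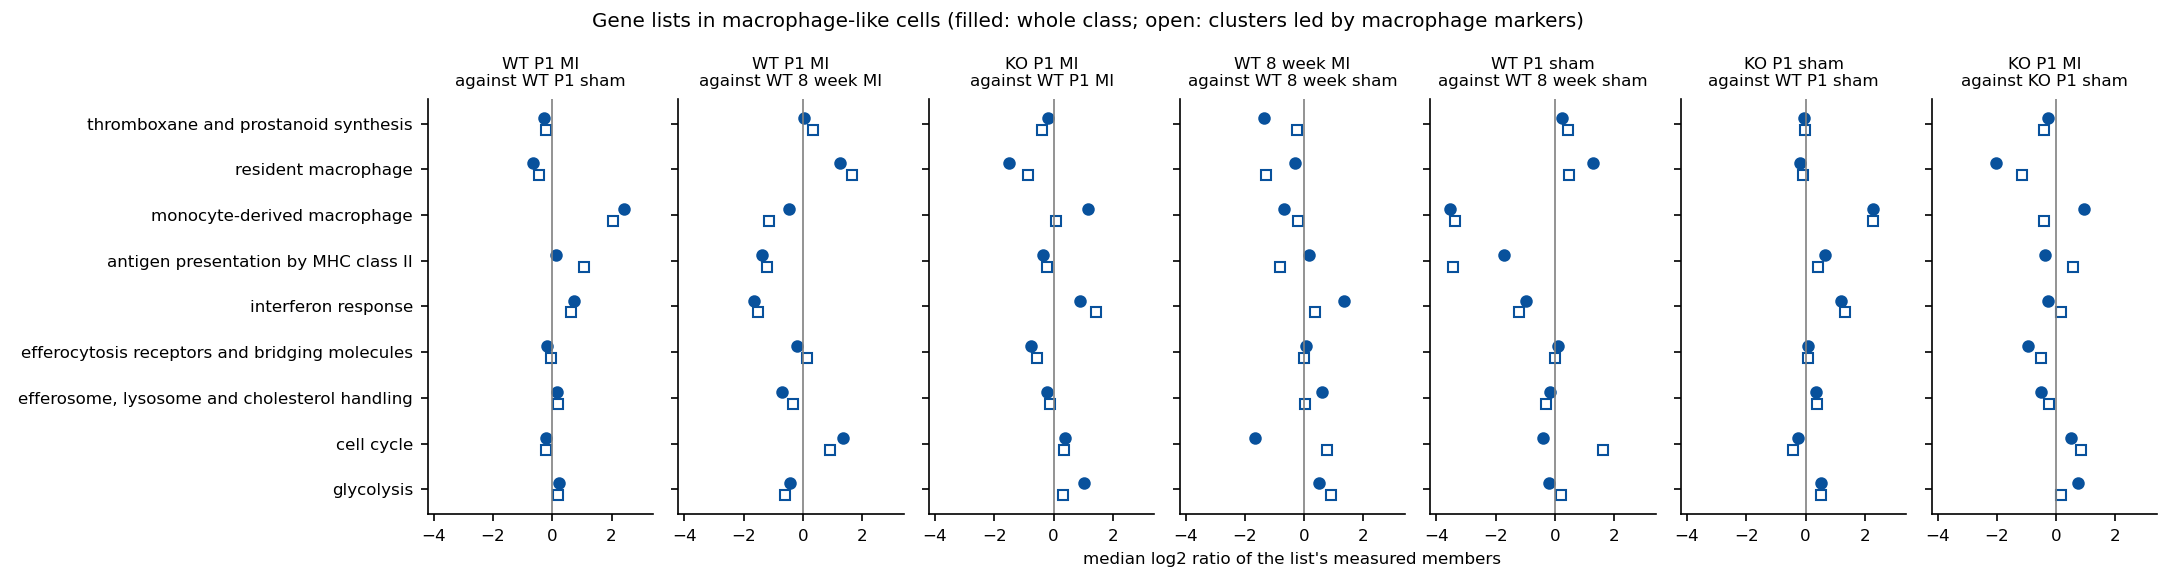
Median log2 ratio (horizontal axis, linear; 0 is no difference, positive is higher in the group named first) of the measured members of 9 gene lists in 7 comparisons of macrophage-like cells; filled circles are the whole class and open squares the clusters led by macrophage markers. The monocyte-derived list is at 2.41 in WT P1 MI against sham and the thromboxane list at −1.37 in WT 8 week MI against sham (0.127 without doublet removal), and the cell cycle list changes side between the symbols in WT 8 week MI against sham and in WT P1 sham against WT 8 week sham.

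In fibroblast-like cells, WT P1 MI exceeded WT P1 sham in complement C3 (0 UMIs in sham, at least 286-fold higher), the chaperone Clu (6.49 ± 0.72), the chemokine Ccl2 (3.84 ± 0.52), the protease inhibitor Timp1 (2.68 ± 0.66, from 45.55 to 78.4 and 471 CPM) and tenascin C, Tnc (1.98 ± 0.43). Of 20 interferon genes 6 rose (13 adjusted over the list alone), of 24 cytokines 8 (12), of 17 fibroblast activation genes 7 (9) and of 28 matrix genes 2 (2). Against WT 8 week MI, the growth factor Igf2 was at least 47.3-fold higher at P1, 12 of 24 cell cycle genes were higher (14), and 16 of 20 interferon and 11 of 17 activation genes were lower (16 and 11). Mertk KO P1 MI exceeded WT P1 MI in Timp1 (3.84 ± 0.56), Lcn2, lipocalin 2 (5.81 ± 0.50), and Il1b, interleukin 1 beta (5.41 ± 0.35), and was lower in the matrix protein Cilp (−5.17 ± 0.56), Cdk1 (−2.85 ± 0.40) and Tnc (−1.69 ± 0.42), with 14 of 24 cell cycle genes lower (15) and 9 of 16 glycolysis genes higher (12). Neutrophil markers moved with the knockout, 13 of 13 being higher with a median of 5.77. Of 12918 genes, edgeR called 220, 2316 and 1031 in these comparisons, and DESeq2 27, 766 and 107. Most of the cells lay in cluster 9 in WT P1 sham, in cluster 18 in WT 8 week MI and in cluster 20, with C3 among its 10 leading genes and 0 cells in WT P1 sham, in Mertk KO P1 MI, so these values compare partly different clusters.

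In endothelial-like cells, edgeR called 34 of 12479 genes between WT P1 MI and sham, among them Cd74, the MHC class II chaperone (2.48 ± 0.58), and Il1b (4.53 ± 0.97). Cd74 rested mainly on replicate 1 (8.99 CPM in sham, 93.1 and 14.9 CPM in MI) and Il1b on replicate 2 (0.418, 0.870 and 14.8 CPM). DESeq2 called 0, with 33 at an unadjusted p under 0.05. Ccl21a, a lymphatic chemokine, rested on replicate 2 (0.435 and 124 CPM). Against WT 8 week MI 352 were called, with Igf2 at least 28.4-fold higher at P1 and Spp1 (−7.33 ± 0.50) and Eno1 (−2.21 ± 0.43) lower. Macrophage transcripts went with Spp1 in the 58 endothelial-like cells of WT 8 week MI, since from 8 week sham to MI Spp1 went from 8.36 to 457 CPM, C1qc from 6.59 to 135 CPM, Ctss from 18.65 to 144 CPM and Alox5ap from 10.3 to 102 CPM. In Mertk KO P1 MI 440 differed from WT P1 MI by edgeR and 60 by DESeq2. Ptgs2 (2.45 ± 0.62), Timp1 (3.21 ± 0.40) and Il1b (6.42 ± 0.52) were higher, and the vascular transcription factor Sox18 (−2.21 ± 0.47) and Eif3j1 (−2.39 ± 0.46) were lower, while 10 of 14 neutrophil markers were higher (11 adjusted over the list alone) with a median of 6.52. Cluster 4 held 182 of the 274 endothelial-like cells of WT P1 sham, against 7 of 58 in WT 8 week MI and 70 of 210 in Mertk KO P1 MI.

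Monocyte-like cells of WT P1 MI had 8 of 10306 genes called against sham, with Mrc1 (6.22 ± 1.26) higher and the chemokine Ccl24 at least 60.4-fold higher. Both rested mainly on replicate 1, with Mrc1 at 306 and 29.9 CPM and Ccl24 at 699 and 42.5 CPM. WT 8 week MI held 16 such cells and was not compared. In Mertk KO P1 MI 52 genes differed from WT P1 MI (31 higher, 21 lower; 5 by DESeq2), with Marco (4.33 ± 0.61), Ptges (3.19 ± 0.52), Ccl5 (3.64 ± 0.63) and the nitric oxide synthase Nos2 (2.55 ± 0.58) higher and Igf1 (−4.42 ± 0.91) and Eif3j1 (−2.69 ± 0.54) lower. Igf1 was at 252 and 12.75 CPM in the WT P1 MI libraries and 4.26 CPM in the knockout, so it rested mainly on replicate 1. Ccl5 and Nos2 had 0 UMIs in replicate 1 and were at 68.3 and 24.0 CPM in replicate 2, against 499 and 94.2 CPM in the knockout. When macrophage-like, monocyte-like and unnamed mononuclear cells were re-clustered, Marco, Ptges, Nos2 and Ccl5 were among the leading genes of 1 sub-cluster. It held 352 cells of Mertk KO P1 MI and 0 and 4 of the WT P1 MI libraries, so these values may compare partly different sub-clusters. Neutrophil-like cells were too few in WT P1 MI replicate 1 (17 cells) for a test. In the knockout, MI against sham gave lower granule genes Ngp (−2.51, −2.54 to −2.48) and Camp (−2.29, −2.34 to −2.24) and higher Ptgs2 (1.26, 1.02 to 1.51). Between the WT sham libraries, the stefin gene Stfa2, a protease inhibitor, was higher at P1 (11.94, 10.75 to 13.98), and Ptgs2 was lower (−3.82, −4.48 to −3.28). Cluster 1 held 2518 of the 2904 neutrophil-like cells of Mertk KO P1 MI and 117 of the 547 of Mertk KO P1 sham, and cluster 7 held 829 of 831 in WT 8 week sham and 33 of 44 in WT P1 sham.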

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

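Chosen only after the results were seen were the tests of the barcode list, of infarction or age as the source of the 8 week MI library's genes, of the cycling cluster, of infarction in the neonate and of sex, and the clusters led by macrophage markers.

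The injury effect in macrophage-like cells differed between ages by edgeR's test of the interaction in 979 genes. Among the genes always named, the difference (log2 fold, neonate minus adult) was 2.52 for Ptgs1, 3.24 for Ptgs2, −2.89 for Hpgds and 2.26 for Ltc4s, which turned to −1.36 without doublet removal. In that setting edgeR called 0 genes (1285 at an unadjusted p under 0.05) and Ptgs1 was at 0.13, Ptgs2 at 0.88 and Hpgds at −1.58. DESeq2 called 167 genes, with an adjusted p of 0.165 for Ptgs1, 1 for Ptgs2 and 0.0187 for Hpgds. In the clusters led by macrophage markers Ptgs1 (1.43) and Hpgds (−1.32) did not pass the test, and without replicate 2 Ptgs2 was at 1.11. The cycling cluster 37 held 42 cells of WT 8 week sham and 1 of each WT P1 library. In that 8 week sham library it had Ptgs1 at 290 and Hpgds at 4.21 CPM, against 97.4 and 111 CPM in cluster 17. The mix of clusters was thus not separated from the age interaction of these genes. Between genotypes the injury effect differed in 113 genes, with Axl at −2.21 (knockout minus WT), which was at −1.31 and not past the test in the clusters led by macrophage markers and had an adjusted p of 0.00236 to 1 over the alternatives tried.

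The WT 8 week MI library stood apart from the other 6 in the same genes of several cell classes, with 124 genes in the 6 classes searched, 19 higher and 105 lower, among the latter Scand1, mt-Nd3, Jund, Gm42418 and Lars2. Reads from the 5' end of transcripts would give more variable receptor segments, but their share was 0.525 times the highest of the others. Barcodes shared with the other libraries numbered 5 where 33.27 were expected from the other pairs, a ratio of 0.15 (Poisson p 1.41e-09), so a different barcode list may be the source. The labels name only the 3' chemistry versions v3 and v3.1 and do not assign them, so a difference in kit was not shown. Infarction or adult age stays open as well, since the 7.26% of genes that moved likewise with infarction at P1 or with age between the sham libraries decide nothing: the genes were chosen to stand apart from those libraries, and infarction in the adult was measured in this library alone. The age comparison after MI and the age interaction, Ptgs1 included, rest on it.

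Neutrophil granule transcripts were higher in macrophage-like cells of WT P1 MI than of WT P1 sham, for 13 of 14 markers. Free RNA would give them to all cells, but in endothelial-like and fibroblast-like cells of the 2 libraries their median level was 0 to 0.0268 times that in macrophage-like cells. Cluster 33 dominates the macrophage-like level, so this ratio does not decide on free RNA in the other macrophage-like cells. Summed in replicate 1, the markers were at 10.4 CPM in each of these 2 classes and at 107 CPM in the clusters led by macrophage markers. The cycling cluster 33 held 99.6% of these UMIs in WT P1 MI replicate 1 with 6 of its 83 macrophage-like cells, and 91.3% in replicate 2 with 118 of 623, so cells of the neutrophil lineage within that cluster may be a source. The granule genes Elane and Mpo were at 5660 and 4106 CPM in it in replicate 1, but at 154 and 42.0 CPM in replicate 2. There 100 of its 118 cells held C1q transcripts, against 4 of 6 in replicate 1. In replicate 2, neutrophil lineage cells were thus not told apart from macrophage-like cells with neutrophil transcripts. The mixed cluster 31, led by Ltf, Camp and Ngp with Mrc1 and Cx3cr1, held 215 further cells of replicate 2. Doublets stay open, since macrophages with such UMIs had 2.13 times or more the UMIs of the others, but 1.62 times in the sham library too. So does infarction in the neonate, since in the clusters led by macrophage markers the summed level was 1.47 times that of the sham library in replicate 1 and 34.4 times in replicate 2 (2510 CPM), where it also went from 14.6 to 236 CPM in fibroblast-like and from 55.8 to 349 CPM in endothelial-like cells, so free RNA may be a part of it there.

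Between Mertk KO and WT P1 libraries, 210 genes differed on the same side in 3 or more of the 6 classes searched, both in sham and after MI, 120 higher and 90 lower. Sex of the pooled animals would need to differ the same way in both comparisons, but over all cells Xist was higher in the knockout in sham (log2 ratio 1.16) and lower after MI (−3.75, and −4.33 and −3.17 against each WT P1 MI library). Loss of Mertk in macrophages stays open: the median change in classes with little Mertk was 1.01 times that in macrophages, but neither this nor the 1.43% of the genes on the X and Y chromosomes decides anything, because the genes had to differ in several classes and on the same side in both comparisons. Alleles of another strain carried along near Mertk could account for some, since 7 of these genes lay within 20 Mb of Mertk (3.33%, against 1.91% of measured genes; Fisher exact p 0.125 across genes, which are not replicates), too few to decide. They include Eif3j1 and Il1b, while Gm50022 and Ifi202b lie outside. Only this interval was tested, so alleles of another strain elsewhere in the genome stay open for the genes outside it. Free RNA from neutrophils was not tested as a source of the 210 genes. From WT to knockout sham, summed neutrophil markers were at 34.6 and 113 CPM in T cell-like, 14.6 and 54.3 in fibroblast-like and 55.8 and 49.5 in endothelial-like cells. After MI they were at 1410, 4123 and 6907 CPM in these classes of the knockout, against 292, 236 and 349 CPM or less in the WT P1 MI libraries.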

How the results depend on the processing

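The clusters led by macrophage markers, the fit without WT 8 week MI, the removal of genes shared with other classes and DESeq2 for the other classes were chosen after seeing the data. No paired analysis was possible because only WT P1 MI has more than 1 library. Leaving out a WT P1 MI library leaves no residual degrees of freedom, so it gives values with no test. Except where said, the cause was not tested. Across alternatives, named genes kept their direction and side of the threshold in 3693 cases, 964 untested values moved, 550 fell below the threshold, 26 passed it and 34 reversed. List medians moved in 739 of 1624 cases and class shares in 345 of 726. WT 8 week MI had the fewest UMIs per cell, and genes of low level there rest on few counts.

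Counts of called macrophage genes, in the order WT P1 MI against sham, WT P1 MI against WT 8 week MI, Mertk KO P1 MI against WT P1 MI, age interaction and genotype interaction, were 219, 2555, 279, 979 and 113. DESeq2 gave 52, 467, 20, 167 and 29. Strict cell filters gave 98, 1573, 40, 456 and 62. Without doublet removal edgeR gave 42, 1118, 3, 0 (1285 at an unadjusted p under 0.05) and 9, and with clusters per library 0 (368), 447, 176, 17 and 3. The clusters led by macrophage markers gave 117, 1530, 47, 252 and 76. With WT 8 week MI out of the fit, WT P1 MI against sham fell to 40, the knockout comparison to 19 and the genotype interaction to 18. RLE scaling gave 109 in the knockout comparison and 61 in the genotype interaction, merging with monocytes 701 in the knockout comparison, and removing genes shared with other classes 183 there, by construction. In the other classes DESeq2 gave, in the same order, 27, 766, 107, 120 and 19 in fibroblasts, 0 (WT P1 MI against sham; 33 at an unadjusted p under 0.05), 60 (knockout comparison) and 2 (genotype interaction) in endothelial cells, and 5 (knockout comparison) and 2 (genotype interaction) in monocytes.

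The thromboxane and prostanoid median in WT 8 week MI against sham (−1.37) was −0.749 at a floor of 100 UMIs, 0.127 without doublet removal, −0.599 with monocytes merged and −0.241 in the clusters led by macrophage markers. In KO sham against WT sham (−0.0642) merging gave −0.436, and in KO MI against KO sham (−0.27) the higher floor gave −0.698.

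Macrophage-like, monocyte-like and neutrophil-like shares moved with the clustering. At resolution 2 neutrophil-like shares were 1.31% in WT P1 sham, 2.25% and 22.8% in WT P1 MI, 0.0361% in WT 8 week MI, 24.9% in KO sham and 54.1% in KO MI, and with clusters per library 0% in WT P1 sham, 34.6% in WT P1 MI replicate 2, 11.3% in WT 8 week MI, 31.4% in KO sham and 53.7% in KO MI. Resolution 0.5 gave 26.3% and strict filters 31.0% in WT P1 MI replicate 2. Strict filters also gave 0% in WT 8 week MI and 62.2% in KO MI, no doublet removal 9.51% in WT 8 week sham and 62.6% in KO MI, and Scrublet's threshold 63.8% in KO MI.

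Some genes reversed (log2). In WT P1 MI against sham, leaving out a WT P1 MI library gave −0.26 (without replicate 2) to 2.57 for Ptgs2 and −0.064 to 2.33 for Thbs1. Iglc1 was 5.43 with strict filters, 3.91 without doublet removal, 2.60 with clusters per library and 5.30 in the clusters led by macrophage markers, and Mzb1 was 2.64, 1.17, 1.09 and 3.46. With clusters per library H2-Eb1, H2-Aa and H2-Ab1 were −0.64, −0.86 and −1.09. Against WT 8 week MI, Ltc4s was −1.38 with monocytes merged, Il1a −1.54 without doublet removal and −1.37 merged, and Arg1 1.46 with clusters per library. In the knockout comparison, strict filters and the clusters led by macrophage markers gave Ltb4r1 −0.33 and −1.24, Vcan −2.28 and −1.80, Arg1 −1.40 and −3.23 and Clec4e −0.16 and −0.15. Merging gave Gpnmb −0.21, and merging and clusters per library gave Tpx2 −0.51 and −0.50, Ccnb1 −0.30 and −0.0098 and Cenpf −0.61 and −0.55. Ifit3 was −0.88 with clusters per library. In the age interaction Ltc4s was −1.36 without doublet removal.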

Other observations

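C3, complement component 3, had 0 UMIs in fibroblast-like cells of WT P1 sham, against 169.9 and 321.5 CPM in WT P1 MI, 651 CPM in Mertk KO P1 sham and 1179 CPM in Mertk KO P1 MI. The fibroblast cluster 20, with C3 among its 10 leading genes, held 0, 17, 223, 136 and 254 cells of these libraries, so the level of C3 was not separated from the absence of that cluster. In WT 8 week sham, C3 was at 704.8 CPM with 0 cells in cluster 20. Saa3 had 0 UMIs in macrophage-like cells of WT P1 sham, against 124 and 311 CPM in WT P1 MI, 222 CPM in Mertk KO P1 sham and 4566 CPM in Mertk KO P1 MI. Because WT P1 sham is the only neonatal WT control, fold changes of these genes against it in WT P1 MI and in the knockout sham share this baseline of 0 UMIs, and the genotype interaction in macrophage-like cells carries that of Saa3. With 1 library, the genotype and this library were not separated.

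Ifi202b, an interferon-inducible gene, had 0 UMIs in macrophage-like cells of all 5 WT libraries and 109 and 98 UMIs in the knockout sham and MI libraries (72.95 and 46.5 CPM). Gm50022, a transcript of no stated function, was at 0, 1.03, 0.533, 0, 0, 60.9 and 68.9 CPM in the order WT P1 sham, WT P1 MI replicates 1 and 2, WT 8 week sham, WT 8 week MI, Mertk KO P1 sham and Mertk KO P1 MI. Whether loss of Mertk or alleles of another strain underlie Ifi202b and Gm50022 was not tested. Re-clustering the 8124 macrophage-like, monocyte-like and unnamed mononuclear cells gave 21 sub-clusters. Sub-cluster 9, led by Marco, Ptges, Saa3 and Nos2, drew 352 of 374 cells from Mertk KO P1 MI, sub-cluster 1, led by Gpnmb, Mmp12 and Ms4a7, drew 98.9% from WT 8 week MI, and sub-cluster 3, led by Prg4 and Alox15, drew 95.3% from WT 8 week sham, so each may be a library as much as a cell state. The partition had adjusted Rand indices of 0.658 and 0.793 with those at resolutions 0.3 and 0.8 and 0.630 with that after thinning.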
